A study of Mus musculus with 6 samples.

How the data were processed

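Cochlear nucleus tissue from both sides of mice at postnatal day 21 was measured after infusion of tetrodotoxin into 1 cochlea by osmotic pump for 24 h, per the labels. Each of the 6 samples was total RNA from a pool of 10 to 12 mice, with 3 ipsilateral and 3 contralateral pools described as biological replicates, hybridised to 1 Affymetrix array each. The deposited values are log2 GCRMA expression values per probe set. The submitters' processing notes name GCRMA, a method that corrects background with probe sequence, normalizes between arrays and summarises the probes of a set, and its version and settings are not given in the sources used here. The log2 scale was read from the values, which ran from 1.40 to 16.0. Because GCRMA shrinks dim probes toward a floor, differences of dim genes are uncertain, and normalization between arrays removes any change common to most genes.

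Groups and replicate numbers came from the sample descriptions. Probe sets were named with the annotation of the array platform held by the repository: 20393 of 22690 probe sets had 1 gene symbol, 691 had several and 1606 had none, and only those with 1 symbol were named. Of the named ones 20364 matched a RefSeq gene (table of assembly GRCm38.p6, used for names only) by Entrez identifier, 29 did not, and 0 symbols needed an update. The 64 control probe sets and 7328 probe sets with a mean log2 value at or below 4 over the 6 arrays were left out, and 15298 were tested. No further normalization was applied.

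The fit was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), ipsilateral minus contralateral over all 6 arrays with no replicate block, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. A descriptive count used an unadjusted p under 0.01 with a log2 difference of 0.5 or more. The design of the comparison, the gene lists and the alternatives were fixed before the data were examined, except for 2 alternatives on choroid plexus content. Most tests of explanations in the closing section were chosen later, as stated there. The 20 gene lists and 13 marker lists were tested with camera of limma at a preset correlation of 0.01 between genes, with the correlation estimated for each list as an alternative, and with fry, adjusted over the lists. A gene was represented by its tested probe set of highest mean, and lists with fewer than 3 tested genes were not tested. List members were also adjusted over the list alone. fry gave no adjusted p below 0.755 for a shift in 1 direction and none below 0.207 for change in either direction.

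Named genes followed a rule of 3 parts. Up to 12 genes per direction were to pass the threshold with the same sign in 3 of 3 replicates. As none passed, the places were filled by smallest unadjusted p within the descriptive set, again with the same sign in 3 of 3 replicates. Up to 3 genes per list were taken by smallest p, of which the text gives the leading ones. Fos, Egr1, Arc, Bdnf and Junb were named whatever their values. Differences are given as log2 values, and a fold as 2 to the power of that difference.

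The series describes infusion of 1 ear and pools by replicate, so the 2 samples of a number were read as the 2 sides of the same mice. The deviations of same-numbered samples from their side's mean correlated at 0.09, 0.04 and 0.57 for replicates 1, 2 and 3, and those of differently numbered samples between -0.37 and 0.30, across tested probe sets. The replicate number as a block was an alternative. Others were no filter, a mean above 6, quantile normalization, median centring, a trended and robust variance, array weights, a plain equal-variance test, leaving out probe sets prone to cross-hybridization, the mean of all probe sets of a gene, an adjusted threshold of 0.1, and leaving out each array and each pair. A pseudocount alternative was not needed for log values.

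The fit and the list test were tested on simulated data with the means and spreads of the 15298 probe sets, 200 of them changed, in 10 runs. At a log2 size of 1 the fit recovered 89.2% of the changed probe sets and at a size of 2 it recovered 99.3%, and 5.47% of calls were false. Camera with the preset correlation recovered a shift of 0.2 planted in 2 lists in 20 of 20 cases and called 0 of 300 other lists. The simulated errors were independent between genes, which real arrays are not.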

Results

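Messenger RNA levels were measured on Affymetrix arrays in the cochlear nucleus, the brainstem nucleus that receives the axons of the auditory nerve, of mice at postnatal day 21. Tetrodotoxin, a blocker of voltage-gated sodium channels that silences action potentials, had been infused into 1 cochlea for 24 h. The nucleus on the infused side (ipsilateral) was compared with the nucleus on the opposite side (contralateral), with 3 biological replicates per side, each a pool of tissue from 10 to 12 mice. No sample came from untreated mice, so a difference between the sides could come from a change on either side. Genes said to have fallen or risen were lower or higher on the infused side than on the other. The deposited log2 values covered 22690 probe sets, and the array medians lay between 5.86 and 5.91. Probe sets with a mean log2 value above 4 were tested, which left 15298 probe sets for 8754 named genes. Arrays give no read depth, so the number of arrays limits the precision, and an exact permutation test of 3 against 3 cannot give a two-sided p below 0.1.

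The comparison asked which genes of the cochlear nucleus are transcriptionally regulated when the auditory nerve is silenced. Genes that neurons induce when they fire were lower on the infused side as groups, with 13 of 17 immediate early transcription factors and 19 of 26 other activity-regulated genes lower (camera of limma, adjusted p = 0.025 and 3.77e-05; adjusted p = 0.754 for both with an estimated correlation). The largest difference among them was that of Fos, a transcription factor induced by neuronal firing. Fos measured 9.43 ± 0.54 on the contralateral side and 7.59 ± 0.17 on the ipsilateral side (log2, SD, n = 3 each), a 3.59-fold lower signal. In the other direction, Ddit4, a stress-induced inhibitor of mTORC1 signalling, measured 7.55 ± 0.51 contralaterally and 8.94 ± 0.17 ipsilaterally, a 2.63-fold higher signal. Both genes differed in the same direction in 3 of 3 replicates, which the rule for naming genes by smallest p required.

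Tested over all probe sets with limma, no single gene passed: 0 probe sets had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 limma gave 364 probe sets, 177 higher and 187 lower on the infused side, where 765 would arise by chance with independent probe sets. This fit left differences between replicates in the error. With the replicate number as a block limma gave 569, 267 higher and 302 lower, also fewer than 765. A plain equal-variance test on the same values also gave 0 after adjustment and 423 at an unadjusted p under 0.05. Requiring an unadjusted p under 0.01 and a log2 difference of 0.5 or more left 39 probe sets for 34 named genes, 21 higher and 18 lower, a description with no error control. That count was 64 without contralateral replicate 3, 91 without ipsilateral replicate 1, 70 without ipsilateral replicate 3, 72 without replicate 1 of both sides and 68 without replicate 3 of both sides. The count past the adjusted threshold was 5 without ipsilateral replicate 1 and 2 without replicate 1 of both sides. These were the choroid plexus genes Kl, Sostdc1, Kcne2, Folr1 and Ttr in the first case and Sostdc1 and Kcne2 in the second, all lower on the infused side and named after their values were seen.

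**Figure D1:**
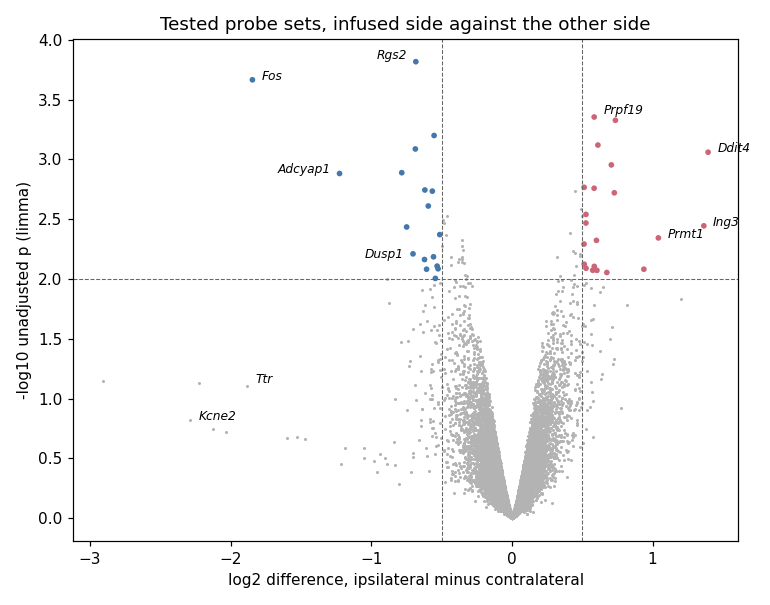
Each point is 1 of the 15298 tested probe sets, with the log2 difference (ipsilateral minus contralateral) on the x axis and -log10 of the unadjusted limma p on the y axis. Dashed lines mark a log2 difference of 0.5 either way and an unadjusted p of 0.01. The 21 probe sets higher (red) and 18 lower (blue) on the infused side include Fos at -1.85 and Ddit4 at 1.39, and none passed after adjustment.

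Of the 12 named genes lower on the infused side, Rgs2 and Rgs4, which switch off G protein signalling, differed by -0.68 (SE 0.09) and -0.51 (SE 0.12) on the log2 scale. Dusp1, a phosphatase that inactivates MAP kinases, measured 9.61 ± 0.35 contralaterally and 8.91 ± 0.10 ipsilaterally (n = 3 each). Adcyap1, which encodes the neuropeptide PACAP, measured 5.87 ± 0.16 and 4.64 ± 0.48, a 2.34-fold lower signal on the infused side. Rem2, a small GTPase that regulates voltage-gated calcium channels, differed by -0.57, and Gpr3, a receptor that keeps cyclic AMP high without a ligand, by -0.62. The others were the gelatinase Mmp2 (-0.75), Arhgap24 (-0.69), the secretory pathway kinase Fam20c (-0.60), the kinase Stk24 (-0.55) and Racgap1 (-0.56), which acts in cytokinesis. The ipsilateral means of Mmp2 (4.22) and Gpr3 (4.50) were dim, near the minimum mean of 4. Other probe sets of Racgap1 (0.08), Stk24 (-0.30, its brighter one) and Rgs4 (-0.34) differed by less, and another of Rgs4 by -0.73.

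The 12 named genes higher on the infused side were led by Ddit4 (1.39), Ing3 (1.36) and Prmt1 (1.04). Ing3, a subunit of a histone acetyltransferase complex, measured 5.27 ± 0.15 contralaterally and 6.63 ± 0.68 ipsilaterally (n = 3 each), and its other probe sets differed by 0.36 and 0.42. Prmt1, an arginine methyltransferase, measured 7.99 ± 0.32 and 9.04 ± 0.44. Gadd45a, which is induced by DNA damage and growth arrest, measured 8.00 ± 0.22 and 8.73 ± 0.19. The splicing factors Prpf19 and U2af1 differed by 0.58 and 0.53, the JNK scaffold Mapk8ip1 by 0.51, and Crcp, a subunit of RNA polymerase III, by 0.51. Pdrg1 differed by 0.61, Morn3 by 0.58, Ier5 by 0.74 and the endosomal sorting protein Stam2 by 0.60. The probe sets of Morn3 (3.96 and 4.54), Ier5 (4.04 and 4.77) and Stam2 (3.72 and 4.32) were dim, near the minimum mean of 4. Other probe sets of Prpf19 (0.14 and 0.10, both brighter) and Ier5 (0.20 for its brightest, and -0.23) did not differ by as much. Nor did those of Stam2 (-0.08 to 0.18) and Pdrg1 (0.18 to 0.53). Ier5 is also in the list of immediate early transcription factors, where its brightest probe set stands for it.

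**Figure D2:**
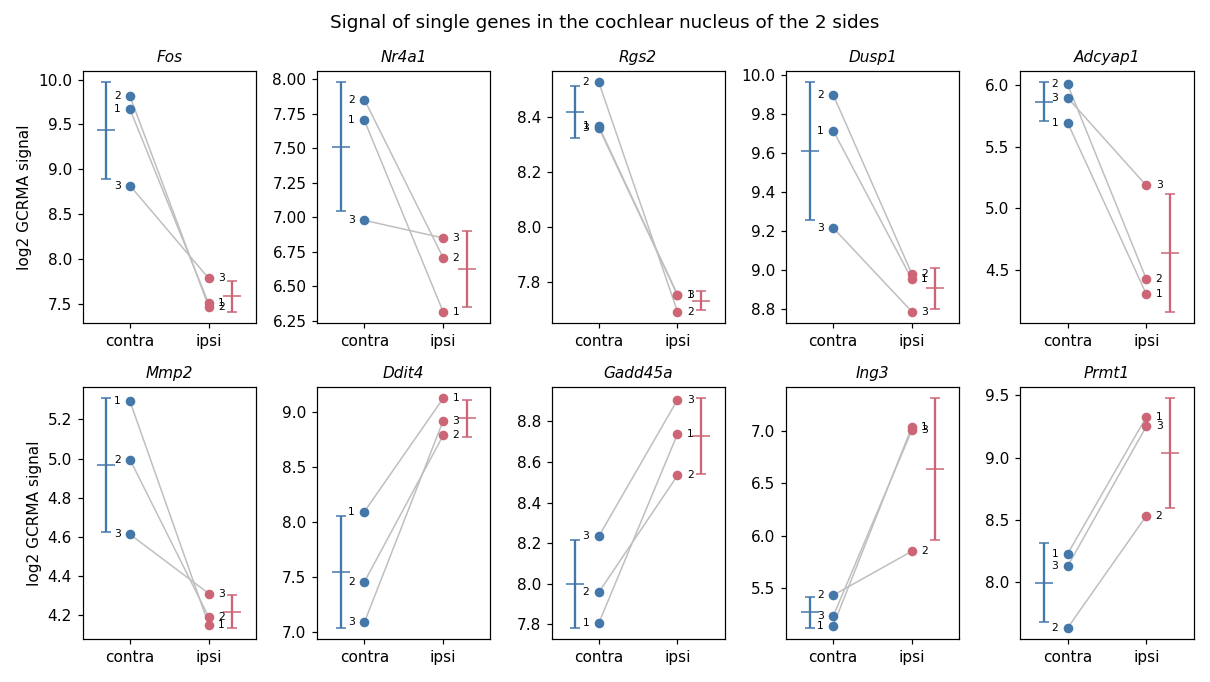
Log2 GCRMA signal of 10 genes on each array (y axis) for the contralateral (blue) and ipsilateral (red) side (x axis). Numbers are replicates, grey lines join replicates of the same number, and bars give mean ± SD of 3 replicates. Each gene's 3 ipsilateral points lie on 1 side of the 3 contralateral ones, as for Fos, with means of 9.43 and 7.59. The genes were named for a small unadjusted p, which favours such a separation. Of all tested probe sets 6.26% showed one, where 10% would by chance.

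The immediate early transcription factors had a median difference of -0.16 on the log2 scale and the other activity-regulated genes one of -0.15. Both lists passed against all other genes with the preset correlation between members (camera of limma, adjusted p = 0.025 and 3.77e-05), and neither did with that correlation taken from the data (adjusted p = 0.754 for both with an estimated correlation). Adjusted over the list alone, 1 transcription factor fell, Fos (adjusted p = 0.00366 in limma), against 0 over all probe sets tested. At an unadjusted limma p under 0.05, 4 of the 17 transcription factors were lower on the infused side and 1 was higher. The nuclear receptor Nr4a1 measured 7.51 ± 0.47 contralaterally and 6.62 ± 0.28 ipsilaterally (n = 3 each), and Ier2 differed by -0.37. Egr1 (7.81 ± 0.92 and 7.20 ± 0.62) and Junb (4.75 ± 0.76 and 3.92 ± 0.61) were lower in 3 of 3 replicates. Their unadjusted limma p was 0.261 and 0.101 without the replicate block and 0.0330 and 0.00929 with it. With the block the adjusted limma p was 0.991 for both. Junb was dim, near the minimum mean of 4, at 3.89 on contralateral array 3 and 3.46 to 4.62 on the ipsilateral arrays. In the other list 4 genes fell when adjusted over the list alone, against 0 over all probe sets: Rgs2 (-0.78 for its brighter probe set), Rgs4, Dusp1 and Scg2, the secretogranin that gives the peptide secretoneurin (-0.36). Arc, a synaptic immediate early gene, measured 5.94 ± 0.18 and 5.73 ± 0.33, and turned to a difference of 0.05 without replicate 1. Bdnf, the activity-dependent neurotrophin, was too dim on average to be tested, at 4.26 ± 0.32 and 3.27 ± 0.46. The mean of the transcription factors lay between 6.40 and 6.70 on the contralateral arrays and between 6.19 and 6.42 on the ipsilateral arrays, so the sides overlapped. That of the other activity-regulated genes lay between 6.98 and 7.24 on the contralateral arrays and between 6.84 and 6.96 on the ipsilateral arrays. With the preset correlation this list passed whichever array or replicate was left out (median from -0.27 to -0.08). The transcription factors did not pass without contralateral replicate 1 (adjusted p = 0.221), ipsilateral replicate 1 (0.180), ipsilateral replicate 3 (0.180) or replicate 1 of both sides (0.443) in limma, and over all alternatives their adjusted p ranged from 8.47e-04 to 0.899. Choroid plexus markers, described further on, were low on ipsilateral arrays 2 and 3, and with their level as a covariate the transcription factors gave a median of -0.20 (adjusted p = 0.0598) and the other list -0.13 (adjusted p = 5.59e-04).

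**Figure D3:**
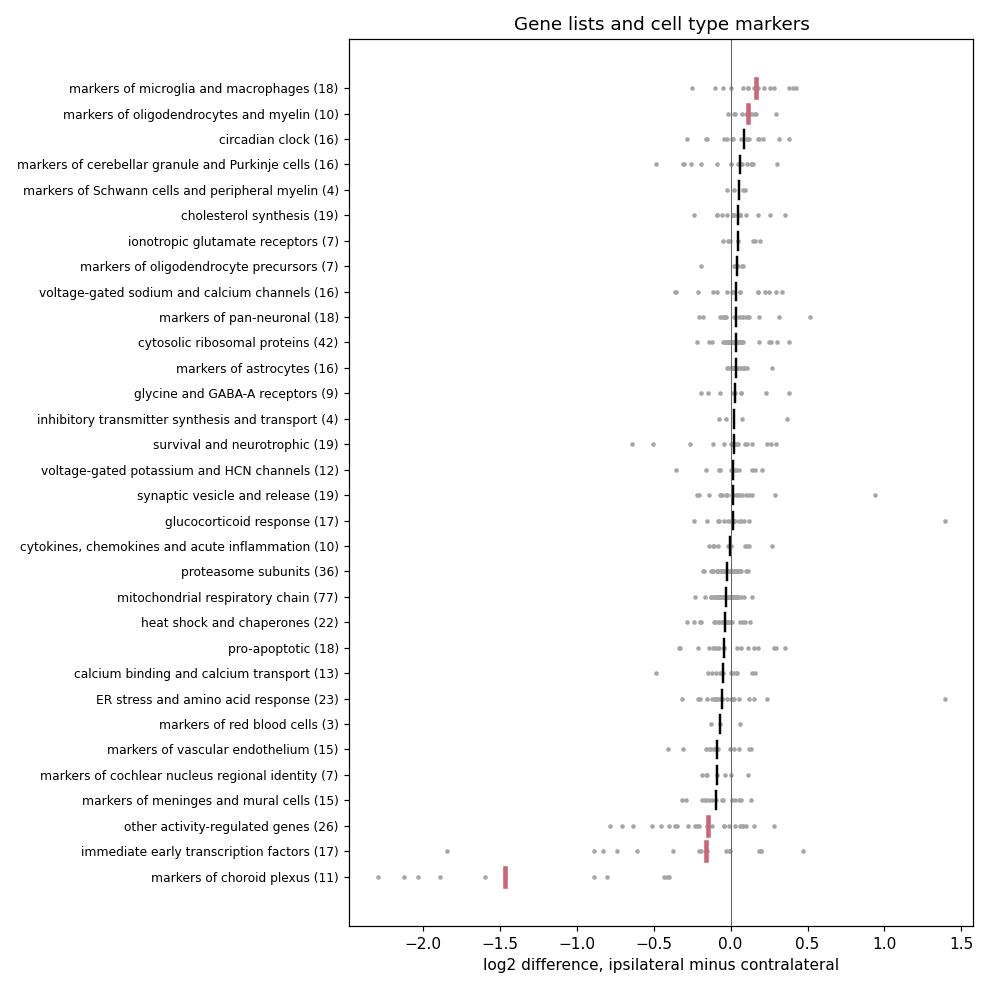
Log2 difference, ipsilateral minus contralateral (x axis), of the members (grey points, 1 probe set per gene) of each gene list or marker list with 3 or more tested genes (y axis, number tested in brackets). Vertical bars are medians, and thick red bars mark the 5 lists that passed camera with a preset correlation. The choroid plexus median is -1.47, and the activity-regulated medians are -0.16 and -0.15.

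Genes of synaptic transmission and excitability did not pass as groups. Of the ionotropic glutamate receptors 4 of 7 were higher (camera adjusted p = 0.424), of the glycine and GABA-A receptors 6 of 9 (0.629), of the genes for inhibitory transmitter synthesis and transport 2 of 4 (0.590), and of the synaptic vesicle and release genes 11 of 19 (0.590). Of the voltage-gated potassium and HCN channel genes 8 of 12 were higher (0.847), of the sodium and calcium channel genes 10 of 16 (0.629), and of the calcium binding and transport genes 6 of 13 (0.514). Calb1, the calcium buffer calbindin, measured 10.27 ± 0.16 contralaterally and 9.79 ± 0.07 ipsilaterally and was the 1 gene of these lists that fell when adjusted over the list alone (adjusted p = 0.0443 in limma), against 0 over all probe sets. Kcnab1, an accessory subunit of Kv1 potassium channels, differed by -0.36, and Cplx2, a complexin that controls vesicle fusion, by 0.94 with SDs of 0.30 and 0.46. The glutamate receptor subunit Grik5 differed by 0.19, the GABA-A receptor subunit Gabrd by 0.38, Gad2, a GABA-synthesizing enzyme, by 0.37 and the calcium channel subunit Cacna2d2 by 0.25.

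Lists for cell death, stress and housekeeping did not pass either. Of the pro-apoptotic genes 8 of 18 were higher on the infused side (camera adjusted p = 0.767), of the survival and neurotrophic genes 14 of 19 (0.611), of the heat shock proteins and chaperones 5 of 22 (0.296), of the ER stress and amino acid response genes 8 of 23 (0.590), and of the glucocorticoid response genes 10 of 17 (0.629). Ddit4 belongs to the last 2 lists and rose in both when adjusted over the list alone (adjusted p = 0.0200 and 0.0148 in limma), against 0 genes over all probe sets. The death receptor gene Fas differed by -0.34, the growth factor gene Igf1 by 0.29 and the small heat shock protein gene Hspb1 by -0.29. Cholesterol synthesis genes were higher in 14 of 19 cases (0.424), with Lss at 0.35, cytosolic ribosomal protein genes in 31 of 42 (0.195), with Rps18 at 0.19, and circadian clock genes in 11 of 16 (0.220), with the clock output gene Dbp at 0.38. Mitochondrial respiratory chain genes were lower in 54 of 77 cases (0.220), with Ndufa7 at -0.13, and proteasome genes in 21 of 36 (0.357), with Psma4 at -0.18. Of the cytokines, chemokines and acute inflammation genes 5 of 10 were higher (0.767), with Icam1 at 0.27. For the potassium channel, pro-apoptotic, survival, ER stress, cytokine and cerebellar lists the median and the mean differed in sign, with means from -0.03 to 0.01. Single arrays mattered for 2 of these lists in limma: the ribosomal genes passed without contralateral replicate 2 (adjusted p = 0.0151) or replicate 3 of both sides (0.0306), over a range of 0.0151 to 0.899, and the cholesterol genes without contralateral replicate 3 (0.0260), over a range of 0.0260 to 0.957.

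Markers of microglia and macrophages, the immune cells of brain tissue, were higher on the infused side for 15 of 18 genes, with a median difference of 0.17 (camera adjusted p = 1.23e-04, adjusted p = 0.754 with an estimated correlation). C1qb, a subunit of complement C1q, measured 8.19 ± 0.22 contralaterally and 8.57 ± 0.08 ipsilaterally (n = 3 each), and the phagocyte proteins Cd68 and Aif1 differed by 0.41 and 0.26. No member passed when adjusted over the list alone in limma, and 3 of 18 had an unadjusted p under 0.05. The mean of these markers was 6.25, 6.32 and 6.59 on the contralateral arrays and 6.58, 6.55 and 6.48 on the ipsilateral arrays. Contralateral replicate 3 thus stood at or slightly above the ipsilateral level, and in replicate 3 the infused side was the lower one. The list did not pass in limma without contralateral replicate 1 (adjusted p = 0.0712), replicate 1 of both sides (0.245) or replicate 2 of both sides (0.0673), and its adjusted p over all alternatives ranged from 2.18e-08 to 0.899.

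Oligodendrocyte and myelin markers were higher for 9 of 10 genes by a median of 0.11 (camera adjusted p = 0.025, adjusted p = 0.813 with an estimated correlation). The myelin genes Mbp, Mobp and Cldn11 differed by 0.17, 0.14 and 0.16. The mean of the 10 markers was 12.12, 12.04 and 12.30 on the contralateral arrays and 12.24, 12.28 and 12.27 on the ipsilateral arrays. In replicate 3 the infused side was thus the lower one. This list passed only without contralateral replicate 3 or replicate 3 of both sides among the fits that left out an array or a pair. It did not pass without contralateral replicate 1 (adjusted p = 0.221) or 2 (0.296), ipsilateral replicate 1 (0.0762), 2 (0.210) or 3 (0.0700), or replicate 1 (0.245) or 2 (0.642) of both sides in limma, with a range of 0.00131 to 0.899 over all alternatives, nor with the choroid plexus level as a covariate (0.258). Astrocyte markers were higher for 14 of 16 genes (0.267), with Sox9 at 0.27, oligodendrocyte precursor markers for 6 of 7 (0.690), with Vcan at -0.20, and Schwann cell markers for 3 of 4 (0.590), with Pmp22 at 0.10. Pan-neuronal markers were higher for 10 of 18 genes (0.296), with the growth cone protein gene Gap43 at 0.51. They passed without ipsilateral replicate 1 (adjusted p = 0.0189), over a range of 0.0189 to 0.971. Vascular endothelial markers were lower for 11 of 15 genes (0.169), with Eng at -0.31, and passed without replicate 3 of both sides (0.0306), over a range of 0.0306 to 0.899. Markers of meninges and mural cells were lower for 10 of 15 (0.296), with Pdgfrb at -0.17, of red blood cells for 2 of 3 (0.838), with Slc4a1 at -0.07, and of cochlear nucleus regional identity for 5 of 7 (0.357), with Lhx9 at -0.16. Of the sex-linked genes only Xist was bright enough to test, at 10.39 ± 0.67 and 10.37 ± 0.86.

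The level of choroid plexus markers differed between arrays of the infused side. The choroid plexus is the secretory tissue that makes cerebrospinal fluid, and it borders the cochlear nucleus in the fourth ventricle. The mean of 11 markers was 8.03, 7.76 and 7.27 on the contralateral arrays and 9.01, 4.94 and 5.20 on the ipsilateral arrays. The transthyretin gene Ttr measured 15.46 ± 0.22 contralaterally and 13.57 ± 2.06 ipsilaterally (n = 3 each), the potassium channel subunit gene Kcne2 6.91 ± 0.33 and 4.62 ± 3.21, and the folate receptor gene Folr1 7.91 ± 0.55 and 5.79 ± 3.16. Averaged over replicates 11 of 11 were lower on the infused side, with a median of -1.47 (camera adjusted p = 9.58e-04, adjusted p = 0.869 with an estimated correlation), and 0 of 11 had an unadjusted limma p under 0.05. Without both ipsilateral arrays low in these markers, an alternative chosen after seeing the data, the median turned to 1.42. The list did not pass without contralateral replicate 1 (adjusted p = 0.0712), ipsilateral replicate 2 (0.310) or 3 (0.252), or replicate 2 (0.642) or 3 (0.175) of both sides in limma, over a range of 2.88e-41 to 0.899. Without ipsilateral replicate 1 the median was -2.86.

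Markers of cerebellar granule and Purkinje cells, from the tissue that overlies the nucleus, were higher for 9 of 16 genes (camera adjusted p = 0.629) with a median of 0.06 and a mean of -0.03. The 3 of smallest p, Calb1 (-0.48), Car8 (-0.31) and Slc1a6 (-0.25), were lower in 3 of 3 replicates. The mean of the 16 markers was 8.89, 8.81 and 9.20 on the contralateral arrays and 8.74, 8.76 and 9.30 on the ipsilateral arrays, so replicate 3 was highest on both sides. Without ipsilateral replicate 3 the list passed, with a median of -0.18 (adjusted p = 0.00565 in limma, over a range of 0.00565 to 0.990). The first principal component held 36.1% of the variance and separated replicate 3 of both sides, at 18.8 and 25.4, from the other arrays, at -13.1 to -8.81. The 3' minus 5' signal of actin was 1.13 ± 0.17 contralaterally and 1.20 ± 0.12 ipsilaterally (n = 3 each, exact permutation p = 0.5), and that of Gapdh -0.04 ± 0.14 and 0.03 ± 0.15 (exact permutation p = 0.6, two-sided). The 18S ribosomal RNA probe sets were lowest on both replicate 3 arrays: the 5' one measured 7.28 contralaterally and 5.72 ipsilaterally there, against 8.53 to 9.22 on the other 4 arrays, and the middle one 7.14 and 6.37 against 8.31 to 8.98.

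**Figure D4:**
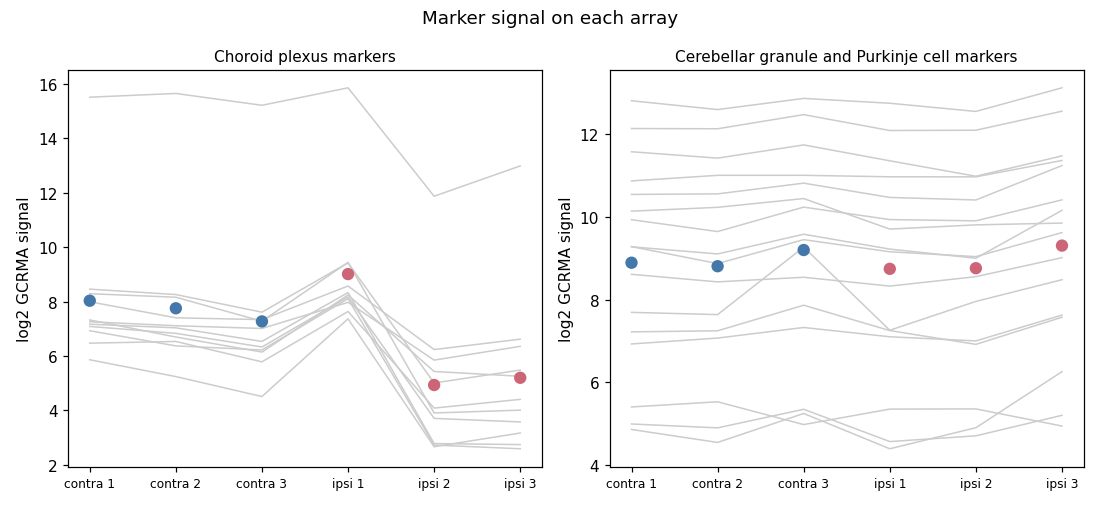
Log2 GCRMA signal (y axis) of choroid plexus markers (left) and cerebellar markers (right) on each of the 6 arrays (x axis). Grey lines are single markers and filled points their mean, blue for contralateral and red for ipsilateral arrays. The choroid plexus mean is 9.01 on ipsilateral array 1 and 4.94 and 5.20 on ipsilateral arrays 2 and 3, and the cerebellar mean is highest on both replicate 3 arrays, at 9.20 and 9.30.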

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

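The choroid plexus alternatives were chosen after seeing the data, and the others before. The count past the adjusted threshold was 0 in each setting that kept all arrays, 0.1 as threshold included, and ranged from 0 to 5 over fits that left out an array or pair. The 39 probe sets of the descriptive count became 25 with a mean above 6 (fewer were tested), 14 with the plain test, 64 with the choroid plexus level as a covariate and 111 without both ipsilateral arrays low in choroid plexus, where a lone array is assumed to vary like the others, and 34 to 91 over single arrays and pairs. The replicate block gave 0 and 47, 30 of them shared, and changed no call. With an estimated correlation, with or without the replicate block, the medians of -0.16, -0.15, 0.17, 0.11 and -1.47 did not pass (adjusted p from 0.754 to 0.899). With array weights the ribosomal list passed at 0.040 and choroid plexus did not at -1.08. With the covariate the transcription factors (-0.20) and oligodendrocyte markers (0.10) did not pass and choroid plexus was -0.082 with its test turned upward. Without both arrays oligodendrocyte markers did not pass (0.10), cerebellar markers passed (-0.16), and choroid plexus (1.42), Ttr (0.40), Kcne2 (1.42) and Folr1 (1.53) turned. The mean of all probe sets of a gene lost the oligodendrocyte call (0.039). Medians over single arrays and pairs ranged from -0.37 to -0.059 for transcription factors, -0.27 to -0.084 for other activity genes, 0.067 to 0.27 for microglia, 0.046 to 0.15 for oligodendrocytes, -2.86 to -0.58 for choroid plexus, 0.0079 to 0.047 for ribosomal genes, -0.028 to 0.15 for cholesterol synthesis, -0.027 to 0.088 for pan-neuronal, -0.11 to -0.038 for endothelial and -0.18 to 0.16 for cerebellar markers. Xist turned with array weights (0.012), with the covariate (0.13) and without both arrays (0.23), and turned without some array or pair (-0.49 to 0.46), as did Slc4a1 (-0.24 to 0.14), Arc (-0.40 to 0.052) and Pmp22 (-0.0024 to 0.20). Kcne2 and Folr1 passed without ipsilateral replicate 1 and Kcne2 without replicate 1 of both sides. The remaining 1257 values of named genes kept their direction and side of the threshold. Beyond the shifts built into a setting, the cause was not tested. Dim probe sets near the GCRMA floor limit what can be measured.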

Other observations

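The tests of choroid plexus content, of replicate 3, of neuron number and of cerebellar tissue were chosen after their results had been seen, and the splits of the arrays and the test of nuclear RNA before. The tests of replicate 3 and neuron number came out open without the replicate block and were then looked at with it, for replicate 3 at first over all 6 arrays. The intervals with and without it are given, and the calls rest on those without.

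The 43 tested activity-regulated genes of both lists averaged 0.23 lower on the infused side (-0.23, SE 0.09, 95% interval -0.47 to 0.00, with the replicate block -0.42 to -0.05, a pairing that no label states), and by -0.30, -0.24 and -0.16 in replicates 1, 2 and 3. The sides nearly met, at 6.748 on contralateral array 3 and 6.746 on ipsilateral array 2. A shift shared by both replicate 3 arrays cancels in a difference between the sides, and an unequal one stays open: without replicate 3 the difference was -0.27, no smaller, with an interval of -0.59 to 0.04 (with the block, at 1 residual degree of freedom, -0.67 to 0.13). Fewer neurons in the ipsilateral pools stay open too, although the pan-neuronal level differed by 0.05 (interval -0.28 to 0.38, with the block -0.17 to 0.27) and the activity level minus it by -0.28 (-0.80 to 0.23, with the block -0.39 to -0.17), negative in 3 of 3 replicates. Choroid plexus tissue stays open beside silencing of the nerve and handling of the ears, both untested: with its level as a covariate the difference was -0.24, no smaller, but 3 residual degrees of freedom left an interval of -0.59 to 0.10, and replicate 1, with more choroid plexus signal ipsilaterally, had the largest drop but is 1 array a side. The 10 splits of the 6 arrays are too few for a share under 0.05: the difference was 0.233 in size for the real split, 0.231 for the highest other and 0.129 for the highest of the 3 others that part every replicate pair, and 1 of 10 splits, the real one, reached it.

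Choroid plexus markers were low on 2 of the 3 ipsilateral arrays. All 11 markers lay below every contralateral array on ipsilateral arrays 2 and 3 and above every contralateral array on ipsilateral array 1. Uneven choroid plexus tissue in the dissected pools stays open, since this count was taken over the markers that prompted it and sets it apart from no other cause. An effect of the infusion common to all 3 pools was to put all 3 ipsilateral arrays below every contralateral array, which was not seen. That explanation stays open too, but the test could not have excluded it. Exclusion asked for 2 ipsilateral arrays above every contralateral array, which was impossible once 2 of the 3 were known to be low. The array against the explanation is a single one, 0.98 above the highest contralateral array. No biological explanation was tested.

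Both replicate 3 arrays stood apart on the first principal component, and 12 of 16 cerebellar markers were higher on both than on every other array, where 2759 of the 15298 tested probe sets were, and 6.67% would be by chance. More cerebellar tissue in the replicate 3 pools is a candidate explanation for that part and stays open, since these markers prompted it. Lower recovery of nuclear noncoding RNA in replicate 3 stays open, although its prediction was not met. Each of 4 nuclear RNAs fixed before the test (Neat1, Meg3, Rian and Snhg11) was to be lower on both replicate 3 arrays than on every other. None was, and their median difference between replicate 3 and the rest was 0.074, where 0 or higher was to count against the explanation. By that rule these 4 RNAs count against the explanation. The call was left open by a further condition that the prediction did not state: the median was to exceed the SD of the 4 differences, and it did not. The 4 differences ran from -0.03 to 0.18. Among other such RNAs, singled out after their values were seen, 5 probe sets of Malat1 differed by -1.75 to -0.40. Those of Xist differed by -1.38, -1.09 and 0.22, and that of Lncpint by -1.94. Protein-coding genes such as Apc (-2.34), Ddx6 (-1.70) and Akap9 (-1.69) differed as much. Litter and day of the pools stay open, while all 6 samples were labelled postnatal day 21, and no biological explanation was tested.

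For the counts the 10 splits are again too few for a share under 0.05. All 10 splits gave 0 probe sets past the threshold with limma. At an unadjusted p under 0.05 limma gave 364 for the real split and 244 to 1756 for the others. The others that part every replicate pair gave 244, 486 and 600, so the real split did not stand out by this count. The descriptive count was 39 for the real split and 235 for the highest other, with 5 of 10 splits as large, and 29 for the highest of the others that part every replicate pair. The split with 235 set contralateral 1, ipsilateral 1 and ipsilateral 2 against the rest, which shows a structure of the arrays other than the side. The real split gave 5 lists past the threshold with the preset correlation, the highest other 8 and the highest that parts every pair 5, with 5 of 10 splits as large.

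The growth hormone gene Gh, singled out after its values were seen, measured 2.80, 6.62 and 2.52 on the contralateral arrays and 4.54, 5.04 and 2.67 on the ipsilateral arrays with 1 of its probe sets, and 3 further probe sets were also highest on contralateral array 2, while the prolactin gene Prl measured 2.53 to 3.08 over the 6 arrays.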
